A study of Mus musculus with 6 samples.

How the data were processed

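Bulk RNA-seq of mouse prostate was analysed in 6 libraries, 3 from mice with a PB-Cre; Pten knockout genotype (PtenKO) and 3 from wild-type mice (WT). PB-Cre is a transgene that expresses Cre recombinase from a probasin promoter, which is active in prostate epithelium, so that a floxed Pten gene is deleted there. Groups were taken from the genotype in the labels, and replicate numbers only name the libraries, since the labels pair none of them. Per the labels' protocols, polyadenylated RNA was sequenced with paired-end reads on an Illumina instrument, and each sample held RNA pooled in equal mass from 3 biological replicates. P-values therefore measure the spread between pooled libraries, which is smaller than the spread between animals. The extraction protocol in the labels speaks of prostate cancer cells, whereas the source and tissue fields give prostate; the libraries are described here as prostate.

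The authors deposited a table of counts per gene and a table of FPKM values for the same 25387 genes, of which the deposited annotation calls 18244 protein-coding and 7143 non-coding. The counts are whole numbers and were not normalized, as the deposited values show. Per the submitters' processing notes, Bowtie 0.12.2 and the builds GRCm39 and mm8 were named, without a role for either build; the role of the aligner, the counter, the annotation release and whether counting used strand are not given in the sources used here. No coordinates are printed, because the reference at hand was of another build. Genes with near-identical copies, such as Reg3b and Reg3g, the Klk1b, H2 and Svs families, Ren1 and Fcgbpl1, are uncertain, since reads can be shared among copies, and so are genes that overlap an antisense gene. The deposited FPKM values were checked against the counts: in all 25387 genes the FPKM equalled the count divided by a whole-number gene length, within 0.01 base, and by the total count of the library. The FPKM table thus carries total-count scaling and no further normalization.

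Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust dispersion, trimmed mean of M-values (TMM) factors, genotype as the only term). The filter filterByExpr (minimum count 10, minimum total count 15) left 16702 genes and removed 8685. P-values were adjusted by the Benjamini-Hochberg method, and every adjusted p for a gene comes from this edgeR test unless another tool is named. A gene was called higher or lower at an adjusted p under 0.05 and an absolute log2 fold change of at least 1.5, the cutoffs stated in the series design text. Within gene lists, a member is said to have risen or fallen when its adjusted p was under 0.05 at any fold, a mark that 28.6% of all genes tested reached upwards and 25.8% downwards. The standard error (SE) of a log2 fold change was its absolute value divided by the square root of the F statistic. Levels are CPM, the share of a gene in the TMM-scaled library size on the usual scale of edgeR, as mean ± SD over n = 3 libraries per group. A named gene that failed the filter was tested in an unfiltered edgeR fit of 25387 genes, and its summed counts were compared by an exact two-sided binomial test, equal to a comparison of 2 Poisson rates, with an exact 95% interval. Such intervals cover counting error only. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1.

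Fixed before the data were examined were the groups, the tests, the alternatives except total-count scaling, 45 gene lists and the rule for naming genes. The rule named Pten and the genes in the design text, 12 genes of the series title or its question, the 10 called genes with the largest change in each direction (mean log2 CPM of at least 4, no overlap between the groups, predicted genes left out), and in each list up to 2 members per direction with the largest change among those that rose or fell (mean log2 CPM of at least 0). Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 45 lists, and again with the correlation estimated from the data. Camera compares a list with all other genes. After the data were seen, camera was also run on 310 KEGG pathways of the deposited annotation with 15 to 300 tested genes, adjusted over these pathways. The list of genes in the design text was chosen by the study on these samples. Counts of members were also made with p-values adjusted over the list alone; in 29 lists these counts were the same, and in the other 16 both are given.

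The alternatives were median-ratio (RLE) and upper-quartile factors, library sizes without the 50 most abundant genes, total counts alone (added after the data were seen), no low-count filter, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited table, the former also with a mean FPKM of at least 1, each library left out in turn, no fold-change cutoff, a test against a log2 fold change of 1.5 (glmTreat), protein-coding genes alone, and fry for the lists. Fold changes from FPKM are on the log2(value + pseudocount) scale, which understates the change of low genes. The edgeR, DESeq2 and limma-voom fits and limma on log2(FPKM + 1) were tested on simulated counts with 200 changed genes among 16702 for this comparison, and the other alternatives were not. Of genes changed by 2 on the log2 scale, edgeR called 80.0%, and of those changed by 3 it called 90.0%, with 5 false calls among the 16405 genes left by its filter. DESeq2 called 89.0% and 92.0% with 20 false calls, limma-voom 79.0% and 86.0% with 5, and limma on log2(FPKM + 1) 51.0% and 64.0% with 3. Camera gave a p under 0.05 for 0 of 100 simulated lists of unchanged genes, which were drawn without correlation between genes. The simulation changed few genes, equally in both directions, whereas 54.3% of genes tested had an adjusted p under 0.05 in the data. It therefore does not test the scaling under so broad a shift.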

Results

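RNA from prostates of PtenKO mice, in which Pten is deleted in prostate epithelium, was compared with RNA from WT prostates, with n = 3 pooled libraries per group. The series asked whether interleukin 10 is raised in prostates that lack Pten, together with macrophage and other immune genes, and its title concerns T cells that carry the chemokine receptor Cxcr6. The PtenKO libraries held 36236339, 39878164 and 38762685 counts (replicates 1 to 3) and the WT libraries 39035610, 39775928 and 39740770. The first principal component, with 79.4% of the variance, separated the genotypes.

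Pten (gene 19211 in the deposited annotation), the targeted lipid phosphatase that opposes PI3K signalling, had 2873, 3358 and 3314 counts in the PtenKO libraries and 3726, 4069 and 3684 in the WT libraries. Its level was 71.6 ± 4.07 CPM in PtenKO and 113 ± 9.52 CPM in WT, a fall of 36.4% (log2 fold change -0.65, SE 0.10, adjusted p = 0.00145) with all 3 PtenKO libraries below all WT libraries. These are counts over the whole gene from whole tissue: the deleted part of Pten is not given in the labels, and reads from other parts of the gene or from cells without Cre do not test the deletion. The change lay below the fold cutoff, and its adjusted p depended on scaling. With total counts alone the log2 fold change was -0.22 and the adjusted p 0.0546, and limma on the deposited FPKM gave adjusted p-values from 0.0575 to 0.0843.

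The libraries differed in how counts were spread over genes. In WT, Fcgbpl1, a gene named for its likeness to the IgG Fc binding protein, took 10.5 ± 1.52% of all counts and the 10 most abundant genes took 23.4 ± 1.35%. In PtenKO the most abundant gene was the mitochondrial COX1 at 1.25 ± 0.162%, and the top 10 took 6.45 ± 1.14%. The TMM factors were 1.18, 1.16 and 1.14 in PtenKO and 0.850, 0.838 and 0.899 in WT. Transcripts of the mitochondrial genome made up 2.75 ± 0.289% of counts in PtenKO and 1.74 ± 0.158% in WT.

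Across 16702 genes tested, 2222 were called higher and 1254 lower in PtenKO. Among called genes with a mean log2 CPM of at least 4 and no overlap between the groups, the 10 largest rises were in the secreted lectins Reg3b (1.08 ± 1.31 CPM in WT and 1760 ± 784 in PtenKO) and Reg3g (3.87 ± 2.48 and 2302 ± 836), their relative Reg1, the mucosal scavenger receptor Dmbt1, the colonic antibacterial protein Lypd8, the brush border cadherin Cdhr5, the neutrophil-attracting chemokine Cxcl5, the myeloid gene Slfn4, and the transcription factors Onecut2 and Hnf4a. Their log2 fold changes ran from 8.23 (SE 0.50) for Hnf4a to 10.65 (SE 1.21) for Reg3b. By the same rule, the 10 largest falls were in Fcgbpl1 (122795 to 11.5 CPM, log2 fold change -13.38, SE 0.61), Ren1, the transglutaminase Tgm4, Tcaf3, the androgen-dependent secretory protein Pbsn, the lipase relative Pnliprp1, Ms4a5, Glb1l3, Pate9 and the gasdermin Gsdma (-8.62, SE 0.31). Dmbt1 was not called with limma-voom (adjusted p = 0.0600). Reads of Reg3b and Reg3g, and of Ren1 and its copies, can be shared. Of all genes tested, 10818 (64.8%) had no overlap between the groups, against 10% by chance. Among the calls 63.9% were higher; with total counts alone, which shift the median log2 fold change of all genes from 0.03 to 0.45, 3157 genes were higher and 864 lower, 78.5% higher. Library sizes without the 50 most abundant genes gave a median of 0.11.

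**Figure D1:**
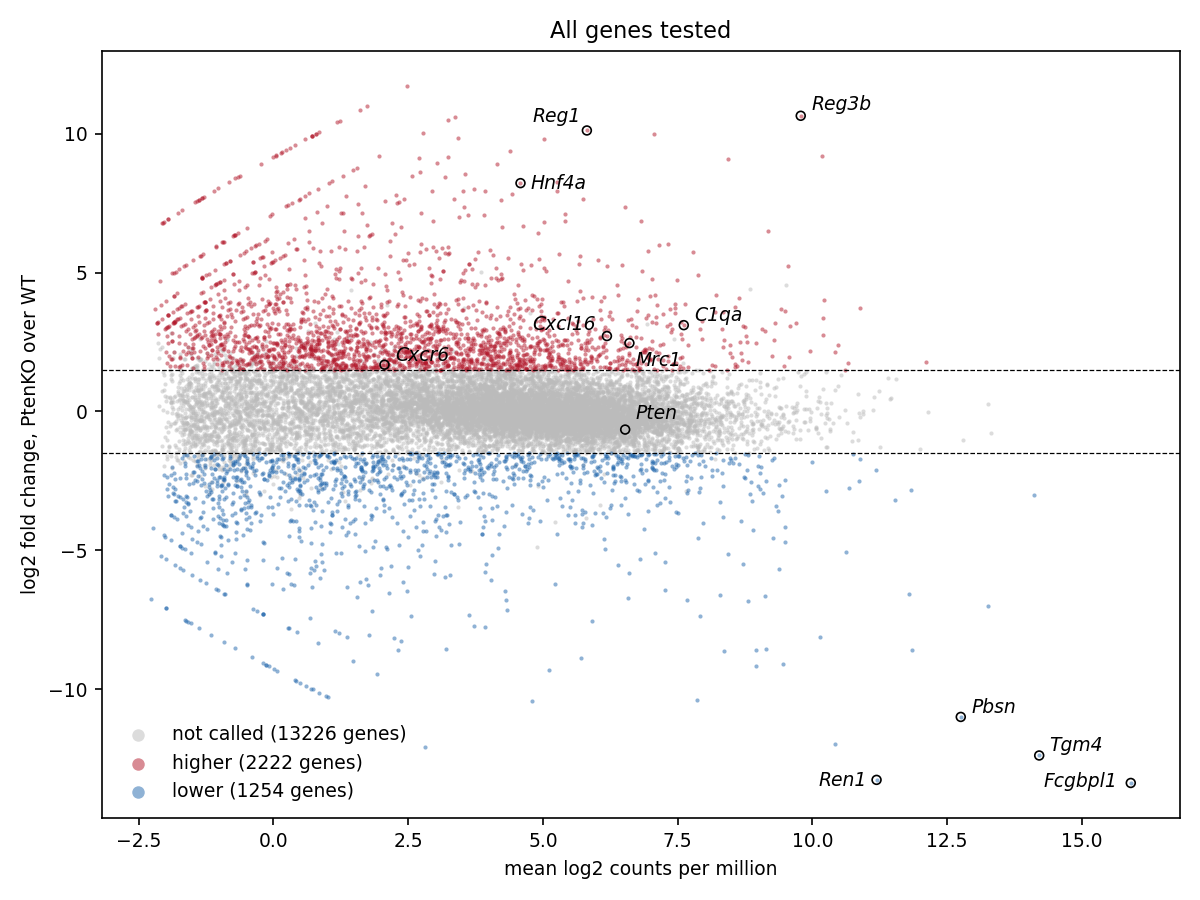
Log2 fold change of PtenKO over WT (vertical axis) against mean log2 CPM (horizontal axis) for 16702 genes, each point a gene; red points are the 2222 genes called higher, blue points the 1254 called lower, and dashed lines mark a log2 fold change of 1.5 in either direction. Fcgbpl1 at -13.38 and Tgm4 at -12.39 lie at the abundant lower right, and Reg3b at 10.65 at the top.

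Of the 8 genes that the design text names, 7 passed the count filter and all 7 rose. Il10 itself (gene 16153), the anti-inflammatory cytokine in question, had 12, 8 and 8 counts in PtenKO and 2, 1 and 0 in WT, too few to pass. In the unfiltered edgeR fit its log2 fold change was 2.72 (SE 1.07) with adjusted p = 0.0707, so it was not called. The summed counts, 28 against 3, gave a ratio of 7.16 (exact 95% interval 2.21 to 36.8, exact p = 7.56e-05), which covers counting error and not the spread between libraries. Limma-voom (log2 fold change 2.59, adjusted p = 0.0194) and total counts alone (3.12, 0.0354) called Il10, while leaving out any library did not (0.0808 to 0.171). On log2(FPKM + 0.1) and log2(FPKM + 1) its adjusted p was 0.00909 and 0.01002, with log2 fold changes of 0.95 and 0.14 that lay below the cutoff.

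Among the macrophage genes that the design text names, Mrc1, the mannose receptor CD206, rose 5.52-fold from 29.8 ± 10.5 to 165 ± 34.2 CPM (adjusted p = 5.64e-04). Cd163, a haemoglobin scavenger receptor, rose only 1.62-fold from 16.7 ± 4.61 to 27.0 ± 5.98 CPM (log2 fold change 0.69, SE 0.25, adjusted p = 0.0494), below the cutoff of 1.5, and PtenKO replicate 1 lay below WT replicate 3. Cd163 did not pass without PtenKO replicate 3 (log2 fold change 0.61), and its adjusted p was 0.116 without PtenKO replicate 2, 0.113 without WT replicate 1, 0.1001 without WT replicate 2 and 0.0519 with RLE factors. The subunits of complement C1q rose 8.63-fold (C1qa), 6.93-fold (C1qb) and 8.54-fold (C1qc), C3 3.43-fold, and the monocyte-attracting chemokine Ccl2 13.3-fold, from 0.366 ± 0.210 to 4.88 ± 1.50 CPM. The study chose these genes on these samples, so their shared direction is not independent evidence; camera gave adjusted p = 2.21e-04 for the 7, and adjusted p = 0.401 with an estimated correlation.

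**Figure D2:**
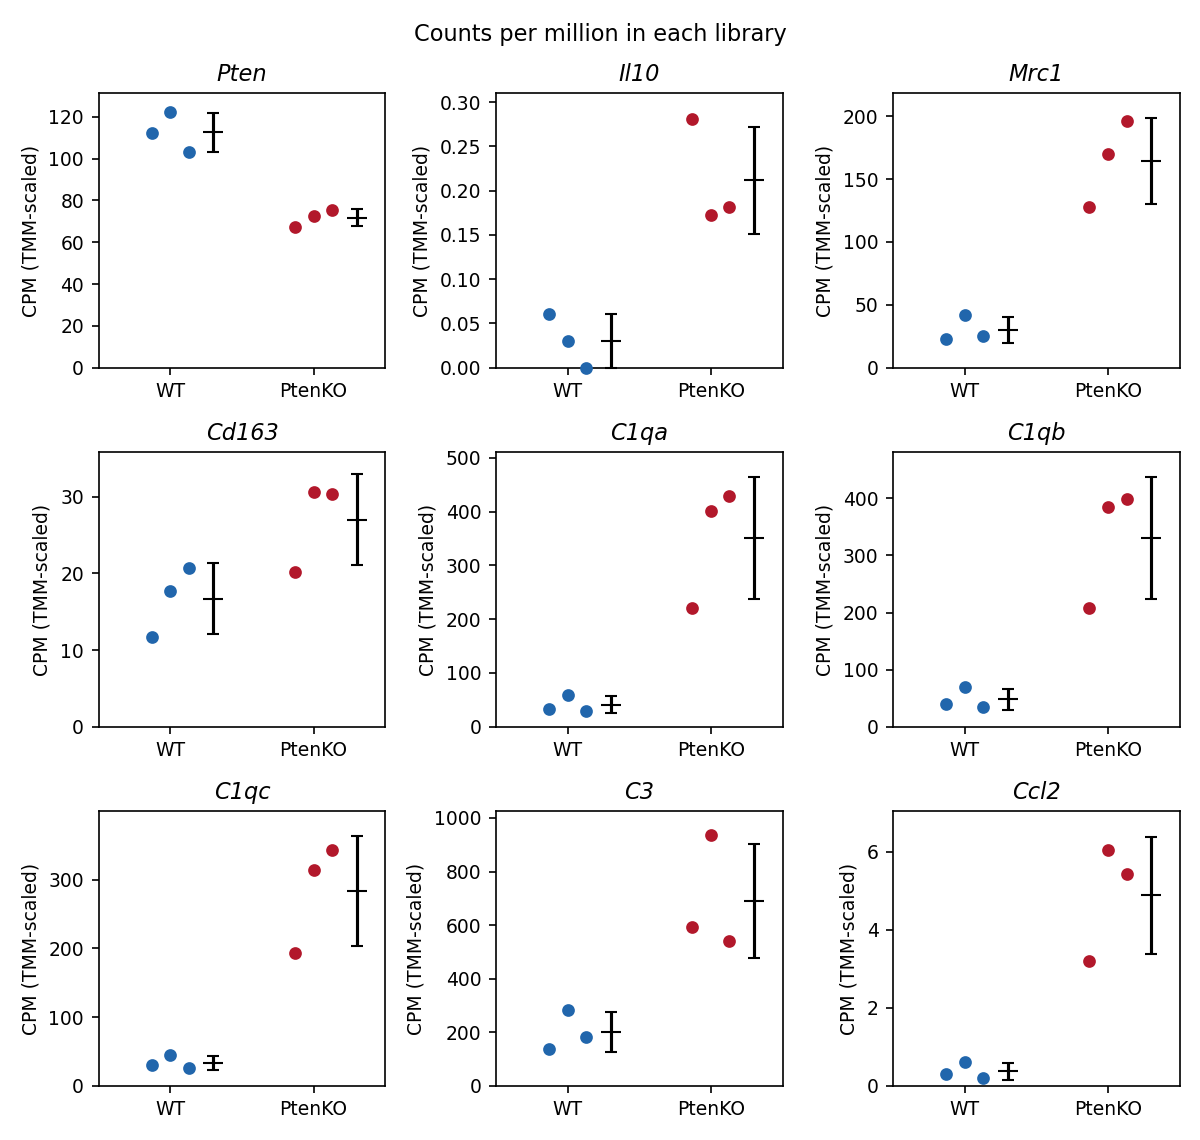
CPM (TMM-scaled, vertical axes from 0) of Pten and the 8 genes named in the design text in the 3 WT (blue) and 3 PtenKO (red) libraries; each point is a library, and black bars give the mean and SD over n = 3. Pten lies lower in every PtenKO library, Il10 stays under 0.3 CPM in each library, and Cd163 overlaps between the groups.

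Macrophage and other myeloid genes rose together. Of 20 macrophage and monocyte genes, 19 rose, with a median log2 fold change of 2.81. The endotoxin co-receptor Cd14 changed by 3.43 (SE 0.12) and the signalling adaptor Tyrobp by 3.14 (SE 0.24). Mertk, a receptor for apoptotic cells, fell from 107 ± 10.98 to 14.0 ± 2.20 CPM (-2.93, SE 0.14). Of genes linked to alternatively activated or tumour-associated macrophages, all 19 tested rose, with the chemokine Ccl17 (5.86, SE 0.53) and osteopontin Spp1 (4.21, SE 0.70) highest. Genes of classical activation rose as well, 10 of 11, with the cytokines Il1b (4.98, SE 0.37) and Tnf (4.67, SE 0.47) highest; the prostaglandin synthase Ptgs2 did not pass (-1.92). Neutrophil genes had the largest median of all lists, 4.83, with 13 of 14 risen. Trem1 and Clec4e, receptors that amplify inflammation, went from 2 counts each over the WT libraries to 373 and 648 over the PtenKO libraries, ratios of 143 (exact 95% interval 39.3 to 1186) and 249 (68.5 to 2057); Il1r2, a decoy receptor, did not pass (0.02). Camera gave adjusted p = 1.52e-10, 1.37e-07, 4.44e-05 and 1.16e-06 for these 4 lists in turn; adjusted p was 0.380 for classical activation and 0.401 for the other 3 with an estimated correlation.

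Of 17 T cell genes tested, 14 rose, with a median log2 fold change of 1.57. The granzyme Gzmk changed by 2.58 (SE 0.47) and perforin Prf1 by 2.53 (SE 0.61), whereas Cd4 (0.97), Cd28 (0.84) and Gzma (0.32) did not pass. Cxcr6 rose 3.22-fold (1.94 ± 0.676 to 6.25 ± 0.539 CPM, adjusted p = 0.00316) and its ligand Cxcl16 6.58-fold (19.2 ± 3.88 to 126 ± 14.0 CPM, adjusted p = 4.70e-05). Cd8a, of cytotoxic T cells, rose 2.66-fold (adjusted p = 0.0430) and the pan-T gene Cd3e 2.07-fold (0.0438). Both lay below the fold cutoff. Leaving out a library raised the adjusted p of Cd8a above 0.05 in 4 of 6 cases (PtenKO replicate 1, 0.0854; PtenKO replicate 2, 0.0727; PtenKO replicate 3, 0.0820; WT replicate 1, 0.0651) and that of Cd3e in 5 (0.0751, 0.0718 and 0.0938 without PtenKO replicates 1, 2 and 3; 0.112 and 0.0751 without WT replicates 1 and 3). For the list, camera gave adjusted p = 0.0111, 0.0574 with total counts alone, and adjusted p = 0.607 with an estimated correlation. Cell-level expression, such as Cxcr6 on CD8 T cells, cannot be read from bulk tissue.

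Several inhibitory receptors rose. Pdcd1, which encodes PD-1, rose 7.97-fold (0.469 ± 0.394 to 3.74 ± 1.69 CPM, adjusted p = 0.0122), Lag3 2.97-fold (0.00399) and Havcr2, which encodes TIM-3, 3.63-fold (0.00198). Ctla4 rose 5.90-fold (0.0415), a call lost without PtenKO replicate 1 (0.0805), PtenKO replicate 3 (0.0992), WT replicate 1 (0.1202) or WT replicate 3 (0.0582). Tigit (log2 fold change 1.32, SE 0.61, adjusted p = 0.103) and Foxp3, the regulatory T cell factor (1.91, SE 0.70, adjusted p = 0.0528), did not pass; without WT replicate 2, their adjusted p-values were 0.0156 and 0.00853. Both also passed with total counts alone, limma-voom and the FPKM values, and Foxp3 with DESeq2 (0.0422), upper-quartile factors and library sizes without the 50 most abundant genes. Over the alternatives, adjusted p ran from 0.0156 to 0.246 for Tigit and from 0.00853 to 0.146 for Foxp3. Adjusted over the 12 question genes alone, Foxp3 had 0.0316 and Tigit 0.0648, and the other 10 stayed under 0.05. The receptor subunits for interleukin 10 rose 4.73-fold (Il10ra, adjusted p = 0.00145) and 2.54-fold (Il10rb, 6.58e-05).

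Of 19 inhibitory receptor and exhaustion-associated genes, 10 rose, with the factor Eomes at 2.23 (SE 0.78), and 3 fell, among them the exhaustion-linked factor Tox (-1.13, SE 0.19) and the nuclear receptor Nr4a2 (-1.05, SE 0.32). Eomes was lost in 4 of the fits without a library, and Nr4a2 in 4 of them, with total counts alone and on the FPKM values. Of 9 regulatory T cell genes, 7 rose (8 adjusted over the list alone), including the costimulatory receptors Tnfrsf9 (3.77, SE 0.52) and Tnfrsf18 (2.18, SE 0.31), and Ikzf4 fell (-2.13, SE 0.26). Neither list passed camera (adjusted p = 0.0640 and 0.0720; adjusted p = 0.672 and 0.520 with an estimated correlation), though both did without WT replicate 2 (0.00956 and 0.0307). Natural killer cell genes rose in 9 of 10 cases (Klra8 3.96, SE 0.46). Mast cell genes rose in 8 of 8, among them the histidine decarboxylase Hdc (2.99, SE 0.63) and the IgE receptor chain Fcer1a (2.87, SE 0.62). Hdc is also a member of the neutrophil list. It had 637, 160 and 362 counts in PtenKO replicates 1 to 3, whereas Fcer1a had 58, 93 and 241. Dendritic cell genes rose in 8 of 12, 9 adjusted over the list alone (Ccr7 2.97, SE 0.76, and Itgax 2.03, SE 0.26). For the natural killer, mast and dendritic cell lists camera gave adjusted p = 0.0192, 0.0413 and 0.0413. With an estimated correlation, adjusted p was 0.521, 0.553 and 0.520. Total counts alone ended all 3 calls (0.0939, 0.155 and 0.136). Without WT replicate 1 the mast cell and dendritic calls were lost (0.0605 and 0.0545), and the dendritic call also without PtenKO replicate 2 (0.0661). Among 12 B and plasma cell genes 2 rose (1 adjusted over the list alone), of which Sdc1 (1.70, SE 0.21) is also an epithelial gene, with camera adjusted p = 0.363 and adjusted p = 0.811 with an estimated correlation.

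Signalling and defence genes rose broadly in PtenKO. Of 31 chemokines 28 rose (29 adjusted over the list alone). Cxcl5 changed by 8.28 (SE 0.68), and Ccl20, which attracts Ccr6-bearing cells, went from 2 counts over the WT libraries to 842 over the PtenKO libraries, a ratio of 323 (exact 95% interval 89.1 to 2672). The homeostatic chemokines Ccl21a (1.30), Ccl25 (-0.03) and Cxcl12 (0.75) did not pass. Of 19 other cytokines 14 rose (15 adjusted over the list alone), including Il1rn, the interleukin 1 receptor antagonist (5.50, SE 0.53), and Tgfb2 (-1.90, SE 0.17) and Il15 (-0.75, SE 0.21) fell; Il15 did not pass with total counts alone, on the FPKM values or without WT replicate 1. Of 14 tested genes of the interleukin 10 family and its targets, 9 rose, among them Bcl3 (3.35, SE 0.28) and Il1rn. Complement genes rose in 20 of 22 cases, with Hc, which encodes C5, at 5.47 (SE 1.01) and the regulator Cfi at 3.91 (SE 0.20). Interferon-stimulated genes rose in 22 of 23 (Oas3 5.30, SE 0.57; Zbp1 5.15, SE 0.49), class I antigen presentation genes in 13 of 14 (H2-Q7 3.96, SE 0.58; H2-Q6 3.47, SE 0.63) and class II genes in 8 of 10 (H2-Ab1 2.38, SE 0.40; H2-DMb1 2.25, SE 0.29). Reads of H2 genes can be shared. Camera gave adjusted p-values from 3.16e-13 (chemokines) to 0.00508 (class II) over these 7 lists, and adjusted p = 0.145 for chemokines and for cytokines, 0.558 for class II and 0.401 for the other 4 with an estimated correlation.

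Products of normal prostate secretion fell. Of 15 luminal secretory genes 12 fell (13 adjusted over the list alone), with a median log2 fold change of -5.66. Tgm4 went from 37811 ± 5731 to 7.02 ± 5.22 CPM and Pbsn from 13788 ± 690 to 6.71 ± 6.52 CPM. The list took 7.54 ± 1.42% of all counts in WT and 0.159 ± 0.0536% in PtenKO. The receptor Gucy2c, a list member better known from intestine, rose (6.39, SE 0.53). By camera the list had adjusted p = 8.14e-06, and adjusted p = 0.401 with an estimated correlation. General luminal genes moved in both directions: 5 of 10 rose, with the keratin Krt8 (1.41, SE 0.14) and the claudin Cldn7 (1.32, SE 0.10) highest, and 3 fell, among them the prostate homeobox genes Nkx3-1 (1120 ± 152 to 3.00 ± 3.72 CPM; -8.55, SE 1.18) and Hoxb13 (-1.68, SE 0.22). Of 21 androgen receptor and androgen-responsive genes, 7 rose (8 adjusted over the list alone), led by Klk1 (5.60, SE 1.06) and Pmepa1 (3.11, SE 0.22). Another 7 fell, 5 of them beyond the fold cutoff with the lowest at -11.01, while Ar itself fell by less (-0.76, SE 0.16). The luminal and the androgen list each had a median above 0 (0.25 and 0.41), a mean below 0 (-0.60 and -0.36) and no call by camera (adjusted p = 0.783 and 0.706; adjusted p = 0.923 and 0.826 with an estimated correlation).

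Of 17 genes of proximal or progenitor-like luminal cells 14 rose, with Wfdc2 (5.24, SE 0.34) and the keratin Krt4 (4.07, SE 0.47) highest. Of 21 epithelial genes of inflamed or injured mucosa 18 rose, with the mucin Muc1 (7.64, SE 0.31) and Reg3g (9.21, SE 0.78) highest, while Agr2, a disulfide isomerase of secretory cells, fell (-3.22, SE 0.19). By camera these lists had adjusted p = 1.48e-07 and 2.41e-12, and adjusted p = 0.244 and 0.238 with an estimated correlation. Of 11 basal epithelial genes 6 rose, with the keratins Krt15 (139 ± 47.2 to 2224 ± 451 CPM) and Krt17 (1.91, SE 0.39) highest, and 2 fell, Dlk2 (-1.78, SE 0.47) and the basal factor Trp63 (-0.72, SE 0.17). Trp63 did not pass with total counts alone or on the FPKM values, and Dlk2 was lost on log2(FPKM + 1) and log2(FPKM + 0.1) and without PtenKO replicate 2 (0.0508) or 3 (0.0512). The basal list was not called by camera (adjusted p = 0.0909; adjusted p = 0.597 with an estimated correlation), but was without WT replicate 2 (0.0274) or WT replicate 3 (0.0490).

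Genes of the secretory pathway and of smooth muscle fell. Of 22 endoplasmic reticulum chaperone and unfolded protein response genes 19 fell and none rose (1 rose adjusted over the list alone or with DESeq2), with a median log2 fold change of -2.08. Creld2 changed by -4.26 (SE 0.27) and the chaperone Hyou1 by -3.41 (SE 0.19), whereas the factor Xbp1 did not pass (-0.17). Of 12 smooth muscle genes 10 fell (11 adjusted over the list alone), with a median of -2.97. Smooth muscle myosin Myh11 went from 1388 ± 207 to 53.2 ± 37.9 CPM and calponin Cnn1 from 475 ± 57.1 to 28.9 ± 19.6 CPM. Fibroblast and matrix genes rose in 20 of 23 cases, with a median of 2.02, led by Timp1 (3.87, SE 0.53) and lumican Lum (3.86, SE 0.51). Camera gave adjusted p = 1.56e-13, 3.41e-08 and 6.36e-06 for these 3 lists; adjusted p was 0.401, 0.401 and 0.521 with an estimated correlation. Of 14 endothelial genes, 4 rose (2 adjusted over the list alone), with the endothelial vesicle protein Plvap (1.63, SE 0.29) and the lymphatic factor Prox1 (1.55, SE 0.49) highest, and Emcn fell (-0.72, SE 0.16). Emcn did not pass with total counts alone or on the FPKM values, and Prox1 was lost with limma-voom, on log2(FPKM + 1) and in 5 of the fits without a library (0.0553 to 0.0999); camera gave adjusted p = 0.428, and adjusted p = 0.826 with an estimated correlation.

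Of 30 proliferation genes 27 rose (28, with 1 fallen, adjusted over the list alone), with a median log2 fold change of 1.46. The mitotic genes Bub1 and Birc5 changed by 2.96 (SE 0.66) and 2.77 (SE 0.29), while Top2a (-0.61), Ccne1 (-0.03) and Cenpf (1.11) did not pass. Of 14 senescence and cell cycle inhibitor genes 11 rose, led by Cdkn2a, which encodes p16 and p19 (0.802 ± 0.376 to 21.4 ± 4.87 CPM; 4.74, SE 0.38), and Plaur (2.98, SE 0.22), and 3 fell, including Gdf15 (-2.82, SE 0.30) and the lysosomal galactosidase Glb1 (-1.39, SE 0.18). The senescence list pools genes that senescence can raise or lower, so its count of risen members does not measure senescence. Among the risen was the lamin Lmnb1 (1.81, SE 0.17), which falls in senescent cells. For the proliferation and senescence lists, camera gave adjusted p = 2.46e-05 and 0.00691, and adjusted p = 0.520 and 0.401 with an estimated correlation. The wider KEGG sets of the deposited annotation were not called: 57 of 153 cell cycle genes rose and 34 fell (camera adjusted p = 0.412), and 63 of 158 cellular senescence genes rose and 38 fell (0.321). With an estimated correlation, the adjusted p of these sets was 0.965 and 0.891. Of 22 FOXO targets and feedback components of PI3K-AKT signalling 10 fell, with the growth factor receptor Igf1r (-2.45, SE 0.29) and its adaptor Irs1 (-2.37, SE 0.12) lowest, and 6 rose, with the lipid phosphatase Inpp4b (1.49, SE 0.20) and Klf2 (1.32, SE 0.21) highest. The median of this list was -0.10, turning to 0.33 with total counts alone; camera gave adjusted p = 0.0530, from 0.0278 to 0.0481 without PtenKO replicate 1, PtenKO replicate 3 or WT replicate 3, and adjusted p = 0.401 with an estimated correlation.

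**Figure D3:**
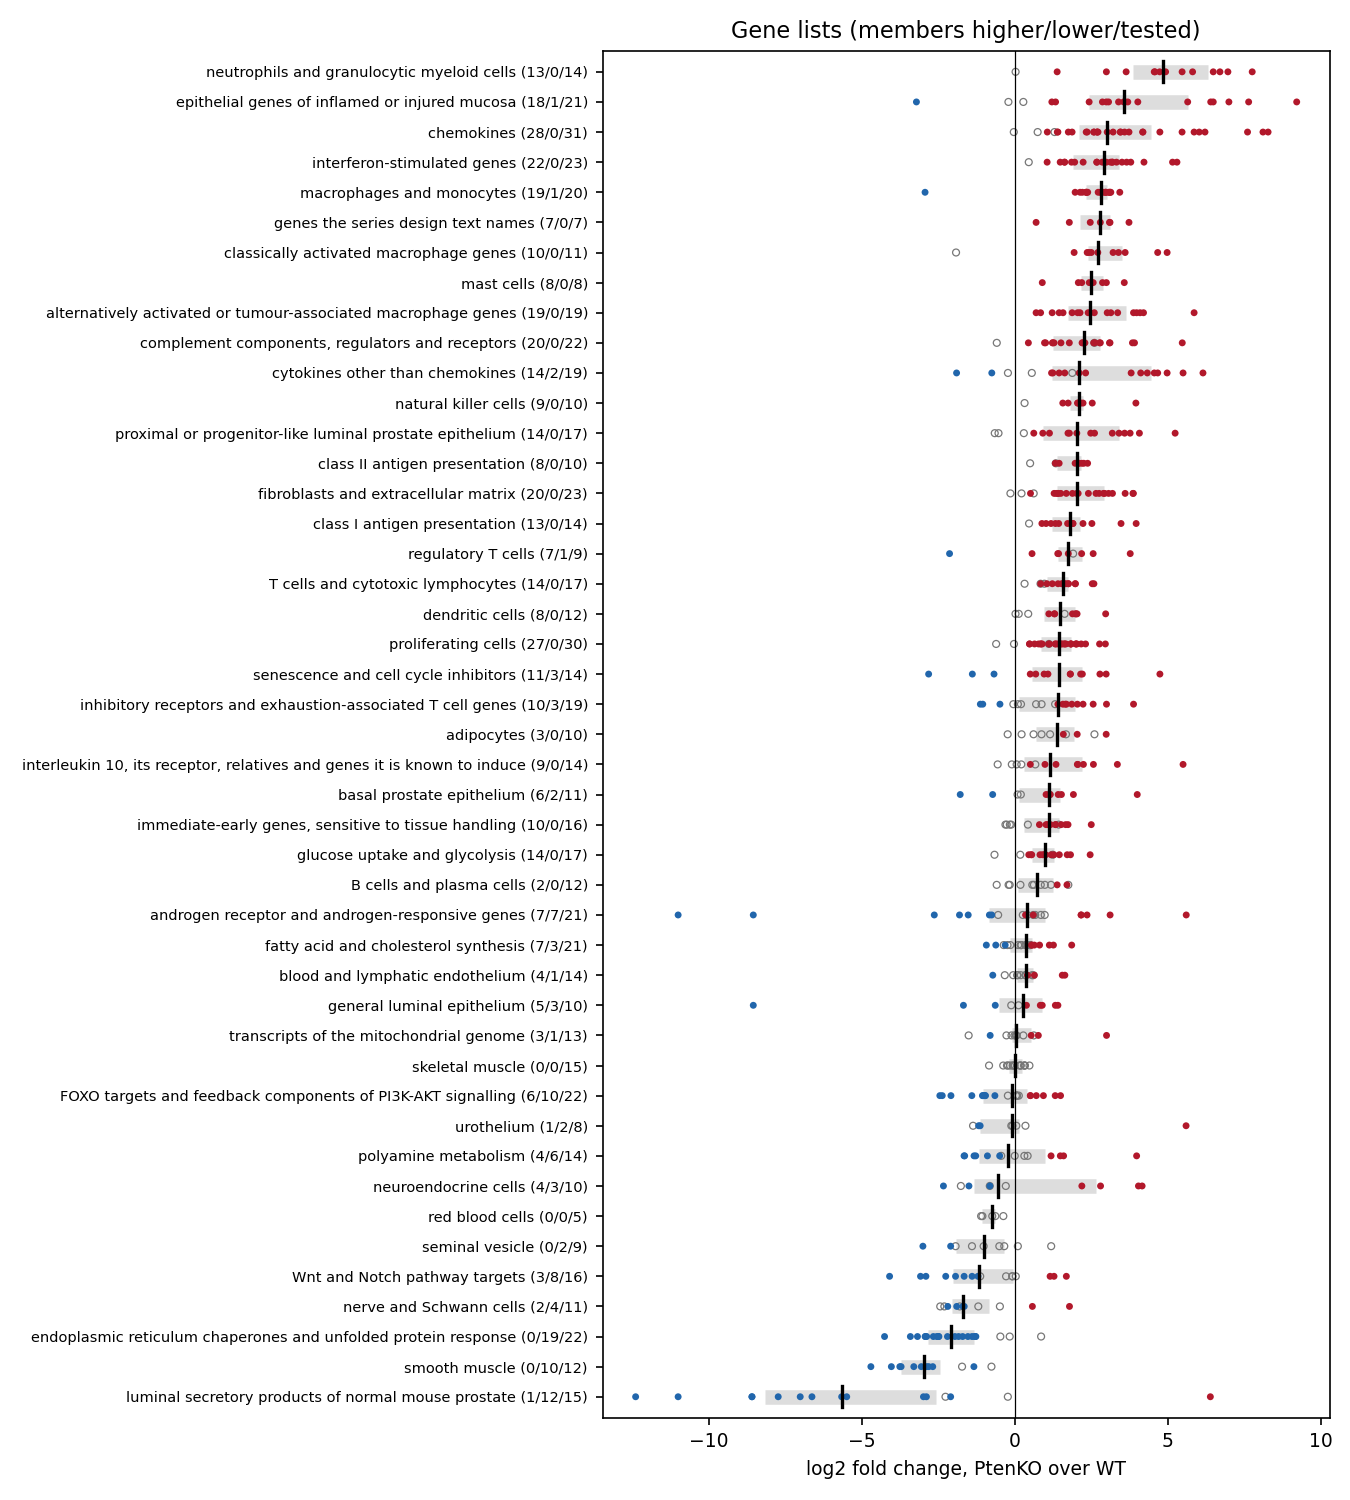
Log2 fold change of PtenKO over WT (horizontal axis) for the tested members of 45 gene lists, sorted by median (vertical axis; counts after each name are members risen, fallen and tested). Filled red and blue points rose and fell at an adjusted p under 0.05, open points did not pass, grey bars span the quartiles and black ticks mark medians, from -5.66 for secretory products to 4.83 for neutrophils.

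Markers of tissue next to the prostate and of tissue handling gave mixed results. None of 15 skeletal muscle genes and none of 5 red blood cell genes passed with edgeR, DESeq2 or limma-voom (medians -0.01 and -0.74); at an unadjusted p under 0.05 the counts were also 0 and 0. The median of the skeletal muscle list turned to 0.39 with total counts alone. Counts of both lists varied widely within each group. Acta1 of skeletal muscle had 16341, 66385 and 1548 counts in PtenKO replicates 1 to 3 and 5322, 8004 and 38345 in WT. Every skeletal muscle gene was lowest in replicate 3 among PtenKO libraries and highest in replicate 3 among WT libraries. Hbb-bs of red blood cells had 1893, 6394 and 7171 counts in PtenKO and 5011, 1561 and 18627 in WT. The lack of a pass thus does not show like amounts of muscle or blood in the libraries. The seminal vesicle list took 1.64 ± 1.03% of counts in PtenKO (2.75, 1.46 and 0.712% in replicates 1 to 3) and 4.08 ± 0.420% in WT. Its genes did not move as a unit: Aoc1l3 had 10335, 6 and 11 counts in PtenKO replicates 1 to 3 and 11308, 9884 and 67 in WT replicates 1 to 3. Sva, Svs3a, Svs3b and Svs6 were likewise higher in PtenKO replicate 1, WT replicate 1 and WT replicate 2 than in the other libraries. These 5 genes were singled out after their values were seen. Of the 9 genes 2 fell, Semg1 (-3.01, SE 0.57) and Pate4 (-2.10, SE 0.30), the latter also a member of the secretory list. Of 8 urothelial genes 2 fell, Gata3 (-1.18, SE 0.13) and Upk1b (-1.13, SE 0.13), and the keratin Krt13 rose (5.60, SE 1.07); this list had a median of -0.10 (0.31 with total counts alone), a mean of 0.26 and a camera direction of down. Of 10 adipocyte genes 3 rose (2 adjusted over the list alone), with Pparg (2.99, SE 0.30) and Plin1 (2.04, SE 0.51) highest, Plin1 being lost without WT replicate 1 or 2. Of 11 nerve and Schwann cell genes 4 fell (5 adjusted over the list alone), with Prph (-2.19, SE 0.72) and Tubb3 (-1.90, SE 0.61) lowest, and 2 rose, S100b (1.79, SE 0.57) and Mbp (0.57, SE 0.11); Prph and Tubb3 did not pass with total counts alone, without the low-count filter or on the FPKM values, and were lost in 3 and 5 of the fits without a library. S100b was lost with limma-voom, on log2(FPKM + 1) and in 5 of those fits (0.0761 to 0.104). None of these 6 lists was called by camera (adjusted p from 0.140 to 0.827; from 0.740 to 0.953 with an estimated correlation). The seminal vesicle list was called without PtenKO replicate 1 (0.0166) and with total counts alone (0.0429), the nerve list without PtenKO replicate 2 (0.0287) and with total counts alone (0.0469), and the adipocyte list without WT replicate 3 (0.0214).

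Immediate-early genes, which respond to tissue handling, rose in 10 of 16 cases, with Fosb (2.50, SE 0.49) and Egr2 (1.74, SE 0.41) highest; Fos (1.44), Egr1 (-0.12) and Atf3 (-0.31) did not pass, camera gave adjusted p = 0.0111, and adjusted p was 0.607 with an estimated correlation. Of 13 transcripts of the mitochondrial genome 3 rose, with ATP8 (3.00, SE 0.54) and ND2 (0.77, SE 0.16) highest. ND4L fell (-0.81, SE 0.16), but did not pass with total counts alone. ATP8 (0.380 CPM in WT) and ND4L (8.53 CPM) were low against COX1 (8870 CPM), and ATP6 (0.05) and ND4 (0.05) did not pass. How reads were assigned among these genes is not given, so the changes of ATP8 and ND4L are uncertain. The median of the list was 0.05, 0.47 with total counts alone. Camera gave adjusted p = 0.797, and adjusted p = 0.925 with an estimated correlation.

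Over all 45 lists, camera called 27, of which 23 pointed up and 4 down. With an estimated correlation it called 0, the lowest adjusted p being 0.145, with 5 lists at an unadjusted p under 0.05; fry called 32. Because the calls by camera depended on the correlation used, the list results above rest on the counts of members that passed their own test. Other splits of the 6 libraries gave 17 to 33 list calls by camera with the preset correlation. Those splits mix the genotypes unevenly and still hold part of their difference, so they do not show how often camera calls lists without one.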

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

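The scaling by total counts was chosen after the data were seen; the other alternatives were planned. No result that passed in the main fit or in an alternative had opposite directions in the 2. Changes of sign in results that passed in neither were not counted. The medians of 4 lists that camera did not call (PI3K feedback, skeletal muscle, urothelium, polyamine) changed sign with total counts alone. The counts of 2222 higher and 1254 lower genes stayed within 1.5 times under RLE factors, upper-quartile factors, library sizes without the 50 most abundant genes, total counts alone, both other filters, DESeq2 (2189 higher and 1353 lower), limma-voom (2221 and 1327), and protein-coding genes alone (1985 and 964). Leaving out each library in turn gave 2103 to 2352 higher and 1150 to 1356 lower genes. With log2(FPKM + 1), 1307 genes were higher and 301 lower, and with a mean FPKM of at least 1, 1317 and 305. With log2(FPKM + 0.1), 2701 were higher and 710 lower. These alternatives change the scaling, the test and the added value together, and the cause was not tested. Without a fold-change cutoff, 4769 genes were higher and 4302 lower, and the test against a log2 fold change of 1.5 (glmTreat), which asks for more by construction, left 1013 and 568.

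Of the 45 lists, camera called 27, 25 with total counts alone, 27 with RLE factors and 25 to 30 without a library. With an estimated correlation it called 0 (5 at an unadjusted p under 0.05), and fry called 32. The cause was not tested.

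The rule for naming gave 145 genes. Other genes that the text mentions, such as Vil1 and Lmnb1, are not in the counts that follow. Over the 145 genes and their alternatives, 2314 values kept their side of the threshold, in 113 the adjusted p rose above 0.05 and in 17 it fell below. For the lists, 399 values kept their side of the threshold, 34 lost a call and 17 gained one. Il10 had 28 counts in PtenKO and 3 in WT, and its adjusted p ran from 0.00909 to 0.171 over the alternatives.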

Other observations

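The tests of the secretory loss and of Il10, the scaling by total counts and the KEGG pathways, and the comparison of Sis and Apoa1 with Vil1 between libraries, were chosen after the results were seen; the other tests of intestine-type genes and the splits of the libraries were chosen before.

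Of 17 genes of glucose uptake and glycolysis 14 rose (15 adjusted over the list alone), with the lactate transporter Slc16a3 (log2 fold change 2.46, SE 0.44) and the aldolase Aldoa (1.82, SE 0.27) highest. Ldha (0.18), Gapdh (1.24) and Pfkm (-0.67) did not pass. Aldoa (2.04 ± 0.468 CPM in WT) and Gapdh (28.2 ± 12.2) lay low against Tpi1 (304 ± 36.1). How their reads were assigned is not given, so the changes of Aldoa and Gapdh are uncertain. By camera the list had adjusted p = 0.00134, and adjusted p = 0.521 with an estimated correlation. The wider KEGG set of glycolysis and gluconeogenesis was not called, with 24 of 55 genes risen, 13 fallen and camera adjusted p = 0.588 (0.925 with an estimated correlation). Of 21 genes of fatty acid and cholesterol synthesis 7 rose, with Idi1 (1.86, SE 0.30) and the regulator Srebf1 (1.26, SE 0.20) highest, and 3 fell, with Elovl6 (-0.93, SE 0.22) and Lss (-0.62, SE 0.11) lowest; camera gave adjusted p = 0.363, and adjusted p = 0.770 with an estimated correlation. Of 14 polyamine genes 4 rose and 6 fell (5 and 7 adjusted over the list alone): the arginase Arg1 (3.98, SE 0.54) and the catabolic enzyme Sat1 (1.59, SE 0.15) were highest, and Arg2 (-1.66, SE 0.24) and the synthase Sms (-1.64, SE 0.11) lowest. This list had a median of -0.22 (0.20 with total counts alone), a mean of 0.09 and a camera direction of down (adjusted p = 0.456; adjusted p = 0.643 with an estimated correlation).

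Of 16 Wnt and Notch target genes 8 fell (9 adjusted over the list alone), with the Wnt targets Nkd1 (-4.09, SE 0.33) and Sp5 (-3.08, SE 0.48) lowest, and 3 rose, with Nrarp (1.68, SE 0.36) and Notch3 (1.28, SE 0.12) highest; camera gave adjusted p = 0.0177, and adjusted p = 0.521 with an estimated correlation. Of 10 neuroendocrine genes 4 rose, with the peptide gene Calca (2.80, SE 0.45) and the granule protein Chga (2.19, SE 0.40) named. Insm1 (4.16, SE 0.76) and Ascl1 (4.04, SE 0.66) rose more, but lay below the level set for naming (0.0193 and 0.0861 CPM in WT). Another 3 fell, with Scg2 (-2.33, SE 0.65) and Syp (12.3 ± 5.11 to 4.33 ± 2.82 CPM) lowest. Scg2 was lost on 2 FPKM scales and without PtenKO replicate 1 (0.0551) or WT replicate 3 (0.0538), and Syp under most scalings and in 5 of the fits without a library. This list had a median of -0.56, a mean of 0.57 and a camera direction of up (adjusted p = 0.797; adjusted p = 0.925 with an estimated correlation).

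Of 310 KEGG pathways in the deposited annotation, camera called 61 up and 13 down; with an estimated correlation it called 0, with 13 at an unadjusted p under 0.05. Among those up were cytokine-cytokine receptor interaction (128 of 205 genes rose, adjusted p = 1.50e-07), chemokine signalling (93 of 168, 1.33e-04), complement and coagulation (43 of 66, 1.48e-04), natural killer cell cytotoxicity (73 of 107, 9.11e-05) and antigen processing and presentation (39 of 66, 0.00646). Among those down were protein processing in endoplasmic reticulum, in which 105 of 159 genes fell, protein export (21 of 27), aminoacyl-tRNA biosynthesis (24 of 44) and the degradation of valine, leucine and isoleucine (28 of 48). Other sets that are wider counterparts of lists called here were not called: ECM-receptor interaction (33 of 79 rose and 15 fell, adjusted p = 0.244), T cell receptor signalling (50 of 111 rose and 26 fell, 0.297), vascular smooth muscle contraction (42 of 117 fell and 27 rose, 0.217) and Wnt signalling (49 of 155 fell and 47 rose, 0.841).

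Most prostate secretory transcripts of the list fell in PtenKO, 12 of 15, whereas Ces1d (-0.23) and Apof (-2.27) did not pass and Gucy2c rose (6.39). Dissection of different lobes would leave products of at least some lobes in place. The weakest fall among Tgm4, Pbsn, Sbp, Spink1 and Msmb, which mark different lobes, was -7.015 (Sbp, SE 1.601). These genes were picked after the results were seen, and other members of the list fell less (Mme -2.99, Spink8 -2.89, Pate4 -2.10). The test thus speaks for the picked genes alone and does not exclude a lobe difference. Fewer luminal cells would lower general luminal genes by a like amount, but 9 of these other than Nkx3-1 had a median of 0.3787, and the lowest was -1.68. Nkx3-1, left out here, fell by -8.55. The 9 genes thus did not fall as the secretory list did. Of all 10 general luminal genes 5 rose and 3 fell, including Krt18 (-0.64) and Hoxb13 (-1.68). Nkx3-1 was left out after the results were seen, so the test does not exclude a loss of luminal cells. Fewer secretory cells and a changed state cannot be told apart by these values. Progenitor-like luminal genes rose (14 of 17), and general luminal genes do not mark secretory cells alone. Scaling left the median of the secretory list at -5.202 or lower. A loss of the differentiated luminal state in cells that lack Pten is a candidate explanation, as a hypothesis found and tested on the same data. It could not be told apart from fewer secretory luminal cells.

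Intestine-type genes such as Vil1 (0.602 ± 0.197 CPM in WT and 84.4 ± 8.29 in PtenKO) rose. Intestinal tissue as the source would bring abundant intestinal transcripts at or above the level of Vil1. The median of their mean levels in PtenKO was 9.242% of that of Vil1, under the bound of 10% set beforehand. The gene at this median was Mttp, which did not pass (7.46 ± 1.18 CPM in WT and 7.80 ± 5.62 in PtenKO). Taken per library, the median was 9.18, 0.685 and 2.98% in replicates 1 to 3 (mean 4.28, SD 4.40), far below Vil1 in each. The margin of 9.242% to the bound was less than this SD. Vil1 was steady at 3212, 4236 and 3820 counts while Sis had 2245, 29 and 114 and Apoa1 1226, 11 and 815. The more abundant Lgals4 (8307, 17543 and 12014) and Clca1 (12549, 22034 and 7473) did not vary in that way. Sis and Apoa1 were picked after their values were seen, so this comparison does not decide the source of the whole pattern. Of 14 of these transcripts tested 12 rose, including Muc2 (7.65, SE 1.32), and Lct fell (-5.41, SE 1.28). Clca1 (313 CPM), Lgals4 (282 CPM) and Fcgbp (403 CPM, against 165 in WT) exceeded Vil1. A smaller admixture of intestinal tissue, above all in PtenKO replicate 1, thus stays open. Of 21 other regulators and brush border genes of gut epithelium 14 were tested and 13 rose (92.86%; camera p = 2.43e-11, and 0.0179 with an estimated correlation), including Elf3 (3.25, SE 0.11) and Hnf4g (3.97, SE 0.41), whereas Spdef fell (-1.47, SE 0.30) and the gut regulators Cdx2 (1, 0 and 1 counts in PtenKO), Isx (19, 3 and 1) and Gata4 (44, 0 and 0) had too few counts to be tested. The gut regulator Cdx1 rose, with 393, 115 and 86 counts in PtenKO replicates 1 to 3 and 0 in each WT library. Ush1c was likewise highest in PtenKO replicate 1 (215, 85 and 70 counts), whereas Elf3 was not (18507, 20541 and 20790). Admixed intestine would raise regulators and brush border genes too, so their rise does not separate it from gut-like expression. Partial gut-like expression in PtenKO prostate is a candidate explanation, as a hypothesis found and tested on the same data.

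Il10 had more counts in PtenKO, where macrophage genes were higher. Counting error alone would leave the ratio of summed counts near 1, but its lower 95% bound was 2.212. A larger share of macrophages without a change per cell would give Il10 the change of the macrophage list, and the difference of their log2 fold changes was -0.08339 with an SE of 1.07 for Il10. A change per cell could lie anywhere within that error, so more Il10 per macrophage and more macrophages cannot be told apart, and other cell types that make Il10 were not tested.

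The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2222 higher and 1254 lower genes, each reached by 1 of the 10 splits, with 0 by edgeR as the highest of the others. For the lists, 4 of the 10 splits had as many calls as the real 27 or more, the highest of the others being 33. Each of those other splits puts 2 libraries of one genotype with 1 of the other. Part of the genotype difference thus stays between its groups and part adds to the spread within them. The counts of those splits therefore do not show what edgeR or camera gives without a difference.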
